A study of Homo sapiens with 3 samples.

How the data were processed

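RNA bound by GST alone, GST-ZFP36L1 wild type and the GST-ZFP36L1 Ala mutant in lysate of J82 bladder cancer cells was sequenced on a BGISEQ-500, with 1 library for each of the 3 proteins. Per the submitters' processing notes, kallisto and DESeq2 were used with the hg19 genome build. Their versions, the annotation release and the role of DESeq2 are not given in the sources used here. The deposited tables give, for 196354 transcripts per library, the estimated count that kallisto assigned to each transcript. They also hold TPM values (transcript abundance scaled to a fixed total), which the authors' pipeline derived from the estimated counts and effective lengths. Per the file headers, the remaining columns are transcript length and effective length in bases. In the GST table the effective length was the transcript length minus 179 for transcripts of over 1000 bases. No fold change computed by the authors was used.

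Transcripts were joined by Ensembl transcript identifier without version to GENCODE 29 (GRCh38), which matched 181857 of them (92.62%), and 93.17% of those had the same length there. The 14497 identifiers not found were left out of the comparisons, with 3.92% of the counts for GST, 3.79% for wild-type ZFP36L1 and 4.20% for the mutant. Estimated counts were summed to 52992 genes and rounded. Genes entered with a mean of at least 10 counts over the 3 libraries, which left 14082. Coordinates are those of GRCh38.

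The library totals were 19137867, 19845386 and 19153483 estimated counts for GST, wild type and mutant, and 14071, 13201 and 14170 genes had at least 10 counts. Genes of the mitochondrial genome took 10.6%, 15.5% and 7.53% of the counts, and the 20 most abundant genes 20.0%, 25.0% and 17.3%, in the same order. Libraries were scaled with TMM from edgeR 4.0.16, whose factors were 1.03, 1.05 and 0.933. Log2 ratios used a prior count of 0.5. The 95% interval of each ratio is an exact Clopper-Pearson interval on the split of the summed counts of both libraries. A gene counted as higher or lower with a ratio of at least 2 in either direction and an interval that excluded 1. A fold against a library at 0 is given as a lower bound against a floor of 3 counts per library. With 1 library per group no p-value across libraries was computed, and none is given.

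The 23 gene lists were chosen before the data were examined: known targets of the ZFP36 family, study targets, the ZFP36 family, hypoxia response, G1/S cell cycle, mitosis, immediate early genes, cytokines and chemokines, the NF-kB pathway, interferon response, p53 targets, housekeeping genes, proteasome subunits, nuclear-encoded respiratory chain, CCR4-NOT and decay machinery, proteins that bind AU-rich elements, mitochondrially encoded mRNAs, abundant non-coding RNAs, urothelial and epithelial markers, mesenchymal markers, markers of leukocytes, erythroid cells and hepatocytes, cytosolic ribosomal proteins, and replication-dependent histones. The median log2 ratio of a list is given relative to the median of all genes, with a 95% binomial order-statistic interval over its genes and its percentile among 10000 random lists matched in 20 bins of expression. Named genes followed a rule set at the same time. It takes the 10 genes with the highest and the 10 with the lowest ratio for each comparison with the wild-type protein, and 5 each for mutant over GST. They were ranked by the interval bound nearest to 0 among protein-coding genes with a symbol. All members of the study targets and the ZFP36 family were added. From each other list at most 4 members per comparison could be named, those with the most counts or those farthest from 0.

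The 3' UTR was that of the protein-coding transcript with the highest mean TPM. Genes with and without UAUUUAU were compared by the difference of their median log2 ratios, with an interval from 1000 resamplings of genes. The difference was ranked among 15460 heptamers found in, and missing from, at least 100 genes. It was also set against 10000 gene sets matched on expression and against sets matched on 3' UTR length and GC content in 10 bins each. A cubic fit on transcript GC content and log2 length, removed by least squares, was added after the data had been seen. For the heptamer ranks a fit on 3' UTR GC content and length, also added after the data had been seen, was removed as a second form. Correlations are across genes. The correlation that shares the GST library was compared with 20 simulated sets of unchanged libraries (Poisson). Sharing of sequence between genes was measured as the percentage of 31-mers found in transcripts of other genes.

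Alternatives tried were DESeq2 1.42.0 size factors, total counts, totals without mitochondrial genes, ribosomal RNA and the 20 most abundant genes, the deposited TPM with a pseudocount of 0.5 and a minimum mean TPM of 1 in place of the minimum count, no minimum and a minimum of 100 counts, protein-coding genes only, single transcripts, counts thinned to the shallowest library, a 4-fold limit, an interval bound of at least 2-fold, the longest annotated 3' UTR, the nonamer UUAUUUAUU, and GST counts split at random. The removal of the GC and length fit and the removal of genes under 3 counts in a library were added later.

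The method was tested on simulated data with 200 altered genes among 14082 in each comparison. Counts were drawn from Poisson distributions, without variation between preparations or errors in assigning reads to transcripts. The rates found therefore cover counting error only. Of 3-fold differences, 97.0%, 94.0% and 97.0% were found for wild-type over GST, mutant over GST and wild-type over mutant, and of 6-fold differences 98.5%, 100% and 97.0%. Of 1.5-fold differences 4.48%, 1.49% and 0% were called. Of 13882 unaltered genes 53, 67 and 64 were called. The interval held the true ratio in 95.7%, 95.7% and 95.9% of genes. Of 100 unaltered simulated lists 4 fell beyond the outer 2.5 percentiles of matched lists, and all 100 lists moved by 0.5 lay above the 97.5 percentile. In a simulation where a linear trend with GC content alone produced a motif difference of 1.16, removal of the fit left 0.0015. The fit holds the same linear term, so this was fixed in advance and does not show how well the fit removes the trend in the data. When a true difference of 0.5 was added, removal of the fit left 0.40, so the fit takes away part of a true effect. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.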

Results

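RNA recovered from lysates of J82, an established human bladder cancer cell line, was sequenced after pull-down with glutathione S-transferase (GST) alone, with GST fused to wild-type ZFP36L1, or with GST fused to the Ala mutant of ZFP36L1. ZFP36L1 is an RNA-binding protein whose zinc fingers recognise AU-rich elements in 3' untranslated regions (3' UTRs), with UAUUUAU as the core site, and which promotes decay of the bound mRNA. The residues replaced by alanine are not given in the labels. There were 3 libraries, 1 per pull-down, so no difference could be set against a replicate. Intervals of single genes cover counting error only, and those of gene lists and of genes with a site cover the spread between genes. The libraries held 19137867 estimated counts for GST, 19845386 for wild-type ZFP36L1 and 19153483 for the mutant. After joining transcripts to genes, 14082 genes had a mean of at least 10 estimated counts. A gene was counted as higher or lower when it differed at least 2-fold after scaling by trimmed mean of M values (TMM) and its 95% counting interval excluded a ratio of 1.

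The comparison of wild-type ZFP36L1 with GST asked which RNAs the fusion protein recovered beyond the GST background. With wild-type ZFP36L1, CXCL1, a neutrophil-attracting chemokine, was 9.19-fold higher (log2 3.20, 3.17 to 3.23), and CSF2, the granulocyte-macrophage growth factor, was 11.9-fold higher (log2 3.57, 3.37 to 3.78). The mRNA of ZFP36L1 itself was 11.2-fold higher (log2 3.48, 3.43 to 3.53). Ribosomal protein, respiratory chain and proteasome mRNAs were lower as groups, and the abundant mRNA of the glycolytic enzyme GAPDH was 13.6-fold lower (log2 -3.77, -3.81 to -3.73). In all, 3587 genes (25.5%) were higher and 4821 (34.2%) were lower. These ratios compare shares of each library, not amounts of RNA. TMM assumes that most genes are unchanged, but 59.7% were at least 2-fold apart here. A lower ratio therefore need not mean that less of that RNA was recovered.

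Of 43 genes listed as known targets of the ZFP36 family, 33 were measured, 27 of them were higher and 1 was lower than with GST. Their median log2 ratio lay 1.98 (95% interval 1.14 to 2.13) above the median of all genes, beyond each of 10000 random lists matched on expression. CXCL2, a chemokine, had 615 estimated counts with GST and 4899 with wild-type ZFP36L1, a log2 ratio of 2.91. CXCL8, also a chemokine, had a log2 ratio of 2.25, and IER3, an early response gene, one of 1.69. PTGS2, which encodes cyclooxygenase, had 31 counts with GST and 129 with wild-type ZFP36L1 (log2 1.96). Of 23 measured cytokines and chemokines, 17 were higher and 2 were lower. This list shares many genes with the known targets, among them TNF, CSF2, CXCL1, CXCL2 and CXCL8, so it is not separate evidence. TNF was 6.61-fold higher (log2 2.72, 2.46 to 3.0), whereas TGFB1 (log2 -1.94) and IL32 (log2 -3.41) were lower. All 3 members of the ZFP36 family, themselves on the list of known targets, were higher. Beside ZFP36L1, ZFP36 stood at log2 2.09 (1.99 to 2.20) and ZFP36L2 at log2 1.94 (1.73 to 2.17).

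The 3' UTRs of several of these mRNAs held repeated UAUUUAU sites (coordinates of the GRCh38 assembly). The 3' UTR of TNF (ENSG00000232810, chromosome 6, 31577538 to 31578336, plus strand) held 8 UAUUUAU sites, with the sequence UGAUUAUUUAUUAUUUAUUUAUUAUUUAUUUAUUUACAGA at 31577997 to 31578036. That of CSF2 (ENSG00000164400, chromosome 5, 132075853 to 132076170, plus strand) held 7, with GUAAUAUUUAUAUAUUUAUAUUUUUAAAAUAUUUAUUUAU at 132076051 to 132076090. The CXCL1 3' UTR (ENSG00000163739, chromosome 4, 73870537 to 73871242, plus strand) held 4, with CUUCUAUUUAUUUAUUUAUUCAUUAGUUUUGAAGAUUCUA at 73870677 to 73870716. The ZFP36L1 3' UTR (ENSG00000185650, chromosome 14, 68787662 to 68789532, minus strand) held 3, with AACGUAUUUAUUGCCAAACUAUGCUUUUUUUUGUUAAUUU at 68788318 to 68788357. HIF1A and E2F1 also held 3 sites each, at 1.40-fold and 2.05-fold over GST, and CCND1 held 1, at 1.11-fold.

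**Figure D1:**
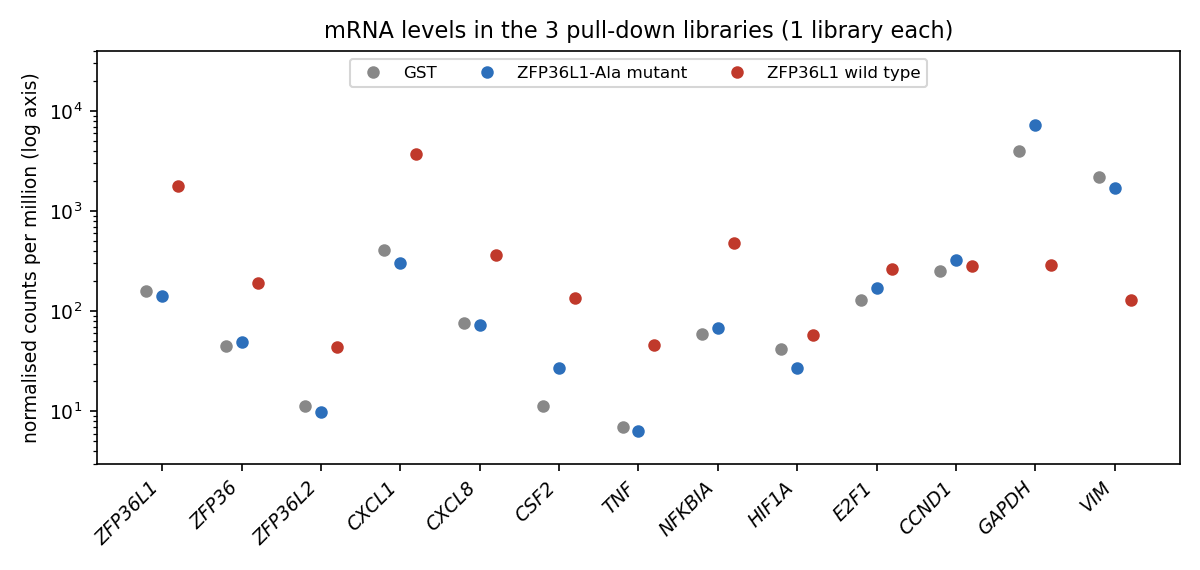
Normalised read counts (CPM) on a log axis for named genes in the GST, wild-type ZFP36L1 and Ala mutant libraries, 1 point per library, so no error between replicates can be shown. CXCL1 lay at 407 with GST, 3737 with wild-type ZFP36L1 and 306 with the mutant, and GAPDH at 3955, 290.2 and 7290, respectively.

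HIF1A, CCND1 and E2F1, which regulate the hypoxia response and entry into the cell cycle, were listed from recollection that the study followed them as targets, which was not checked against its publication, and they are not independent evidence. E2F1 was 2.05-fold higher with wild-type ZFP36L1 than with GST (log2 1.03, 0.96 to 1.10). HIF1A (log2 0.48, 0.35 to 0.61) and CCND1 (log2 0.15, 0.09 to 0.20) lay above 1 but under 2-fold. Among 26 measured hypoxia response genes, 10 were higher and 5 lower. The list lay at 0.92 (-0.23 to 1.28) relative to all genes, at the 98.3rd percentile of matched lists, and at 0.31 with a fit on transcript GC and length removed. The transcriptional repressor MXI1 was higher (log2 2.85), while the glycolytic enzymes ENO1 (log2 -3.96) and TPI1 (log2 -3.16) were lower. Of 27 immediate early genes, which answer growth signals within minutes, 12 were higher and 4 lower, at 0.96 (-0.15 to 1.90) relative to all genes and 1.52 with the fit removed. This list shares DUSP1, IER3, FOS, MYC and ZFP36 with the known targets, so it is not wholly separate evidence. DUSP1, a phosphatase of MAP kinases, was higher (log2 2.41), as were CYR61 (log2 2.33) and CTGF (log2 2.48), both secreted matricellular proteins, and IER2 was lower (log2 -3.94).

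Cytosolic ribosomal protein mRNAs took smaller shares with wild-type ZFP36L1: 58 of 80 were lower than with GST and 2 were higher. Their median was -2.20 (-2.59 to -1.61) relative to all genes. RPL27 (log2 -4.02) and RPL12 (log2 -3.78) were lower, whereas RPL15 had a log2 ratio of 0.75. Of 40 nuclear-encoded respiratory chain genes, 28 were lower and 4 higher, with a median of -2.21 relative to all genes. NDUFS5, a subunit of complex I, was 18.3-fold lower (log2 -4.19, -4.33 to -4.06), while NDUFB4 of the same complex was higher (log2 1.13). Of 30 proteasome subunits, 21 were lower and 1 higher, with a median of -2.04 relative to all genes, and PSMC5 had a log2 ratio of -4.10. The ratio of wild-type ZFP36L1 to GST fell with the GC content of the transcript across all 14082 genes (Spearman rho -0.59, across genes, which are not independent replicates). The median transcript GC content was 50.3% for ribosomal protein genes, 50.7% for respiratory chain genes, 48.1% for proteasome genes and 51.8% for the known targets. With a fit on transcript GC and length removed, the medians relative to all genes were -1.09 for ribosomal proteins, -0.83 for the respiratory chain, -1.93 for the proteasome and 2.34 for the known targets.

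Other groups held genes on both sides. Of 30 mitosis genes, 10 were higher and 8 lower: MAD2L1, a spindle checkpoint protein, was higher (log2 2.83) and the kinase AURKB lower (log2 -3.56). Of 29 genes of the G1/S transition, 10 were higher and 7 lower, and within the MCM replicative helicase MCM2 was higher (log2 1.49) and MCM7 lower (log2 -4.06). Of 20 p53 targets, 8 were higher, such as PLK2 (log2 1.88), and 5 lower, such as TP53I3 (log2 -3.74). In the NF-kB pathway, 7 of 19 genes were higher and 6 lower. The inhibitor NFKBIA was 8.17-fold higher (log2 3.03, 2.94 to 3.12), and NFKB2 was lower (log2 -3.08). Of 25 genes of the CCR4-NOT complex and other mRNA decay machinery, 9 were higher and 9 lower, with the deadenylase CNOT6 at log2 2.09 and the decapping scaffold EDC4 at log2 -5.09 (-6.66 to -4.05). Of 14 proteins that bind AU-rich elements, 5 were higher, including PTBP1 (log2 1.53), and 2 lower, including HNRNPD (log2 -1.66).

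**Figure D2:**
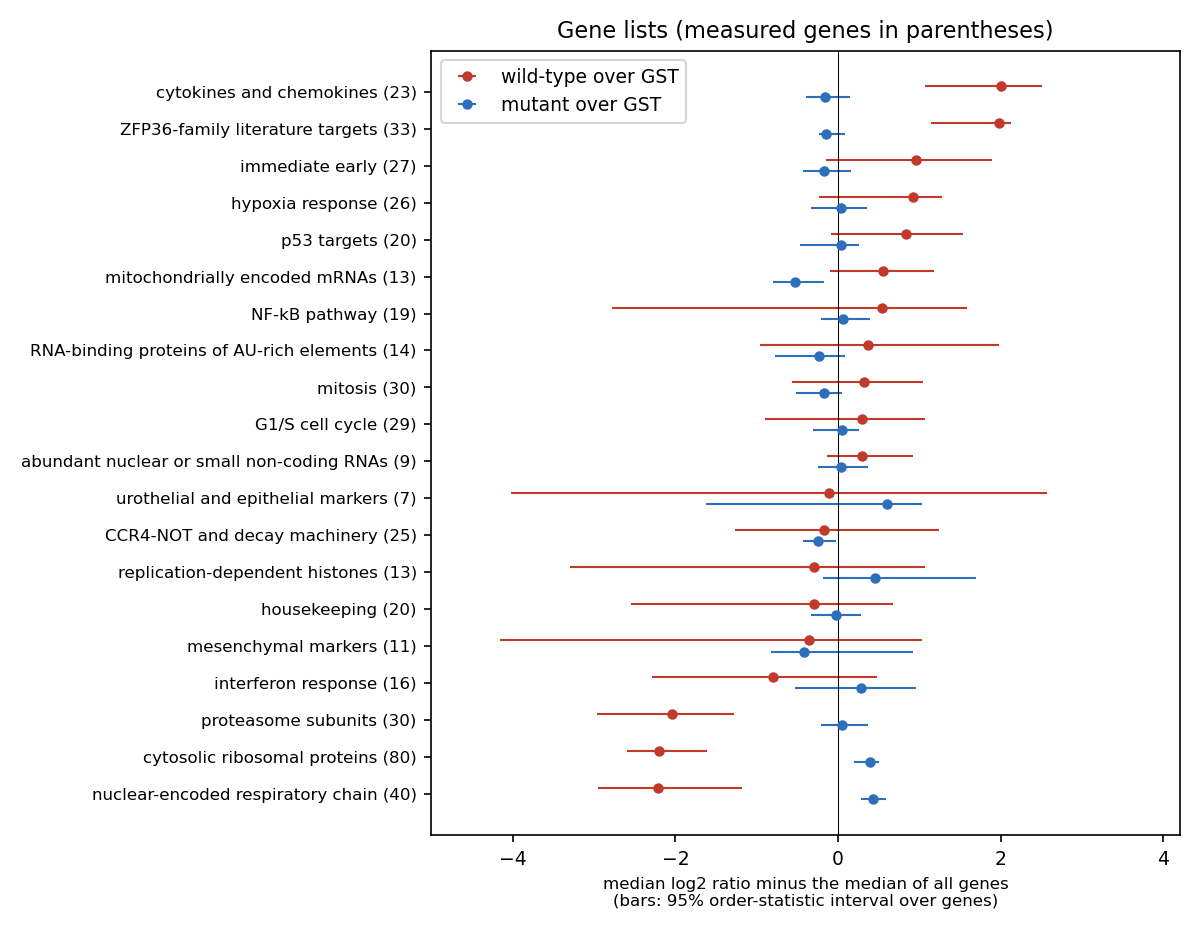
Median log2 ratio of each gene list minus the median of all genes, with 95% order-statistic intervals over the genes of the list, for wild-type ZFP36L1 over GST and mutant over GST. Known targets stood at 1.98 with wild-type ZFP36L1 and -0.14 with the mutant, and ribosomal proteins at -2.20 and 0.40.

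Genes with a UAUUUAU site in the 3' UTR were higher with wild-type ZFP36L1 relative to genes without one. An annotated 3' UTR was available for 11694 genes, of which 3600 held the site. Their median log2 ratio of wild-type ZFP36L1 to GST was 0.94, against -0.69 for the other 8094, a difference of 1.63 (1.56 to 1.70, genes resampled). Among genes with the site 47.1% were higher than with GST, and among genes without it 17.8%. Random gene sets matched on 3' UTR length and base composition gave a median difference of 1.18 and at most 1.28. The difference was 0.65 (0.60 to 0.71) once a fit on transcript GC and length was removed. Of 15460 heptamers ranked by this difference as measured, UAUUUAU came 12th, behind other A- and U-rich heptamers led by UUUUAAA at 1.90, and it was 4th of the 21 heptamers with 5 U and 2 A. With the fit on transcript GC and length removed it ranked 1st of the 15460, followed by CCGUCCG at 0.60, a heptamer found in 103 genes. With a fit on 3' UTR GC and length it ranked 2nd, at a difference of 0.51. UUCGGAC, found in 109 genes, came 1st there at 0.53, and CCGUCCG came 3rd at 0.51.

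Comparing the Ala mutant with GST asked whether any RNAs took a larger share with the mutated protein than in the background. The composition of the RNA recovered with the mutant lay close to that with GST. The Pearson r across genes was 0.96 between their log2 CPM values (read counts scaled to library size), against 0.79 for GST with wild-type ZFP36L1. Because counts were scaled to library size, the amount of RNA that each protein recovered cannot be read from these values. The known targets stood near the background: 1 of 33 was higher (CSF2, 2.39-fold, log2 1.25, 1.02 to 1.5), 1 was lower (PTGS2, log2 -1.59), and the list lay at -0.14 (-0.24 to 0.08) relative to all genes. CXCL1 had a log2 ratio of -0.41 (-0.46 to -0.36), TNF one of -0.14 (-0.52 to 0.24) and CXCL8 one of -0.07 (-0.18 to 0.04). ZFP36L1 mRNA stood at log2 -0.19 (-0.26 to -0.11) and ZFP36L2 at log2 -0.19 (-0.49 to 0.10), and ZFP36 stood at log2 0.13 (-0.01 to 0.27) under TMM and -0.09 when scaled to total counts without the most abundant genes. The study targets stood at log2 -0.64 (-0.81 to -0.47) for HIF1A, 0.41 (0.33 to 0.48) for E2F1 and 0.35 (0.29 to 0.40) for CCND1. In all, 1268 genes (9.0%) were higher and 722 (5.13%) lower. The name of the deposited table carries another run code for GST than for the wild-type and mutant libraries, so a difference between runs cannot be told apart from GST in either comparison with GST. Wild-type and mutant libraries share a run code, so the GST run does not enter their comparison. Genes with a UAUUUAU site still exceeded the others there by 1.99 (1.90 to 2.08), with 1 library per protein.

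Ribosomal protein mRNAs were higher with the mutant in 12 of 80 cases and lower in none, at 0.40 (0.20 to 0.51) above all genes, as were 7 of 40 respiratory chain genes, at 0.42 (0.28 to 0.59), with none lower. Examples from the respiratory chain were the complex I subunits NDUFS8 (log2 2.10) and NDUFV1 (log2 1.49). Both list medians stayed above 0 under each of the scalings tried, but 8 ribosomal protein genes were at least 2-fold higher when scaled to total counts and 6 with totals without the most abundant genes, and respiratory chain genes numbered 6 and 5. With the fit on GC and length removed, the list medians were 0.15 for ribosomal proteins and 0.20 for the respiratory chain. Larger shares were higher in smaller lists whose intervals included 0: 5 of 13 replication-dependent histones with none lower, in each scaling, at 0.45 (-0.18 to 1.69) relative to all genes, and 4 of 16 interferon response genes with none lower under TMM, at 0.28 (-0.53 to 0.96), or 3 higher and 2 lower with totals without the most abundant genes. All 13 mitochondrially encoded mRNAs had ratios under 1 in each scaling, with a median of -0.53 relative to all genes and 2 at least 2-fold lower, MT-ATP8 (log2 -1.52) and MT-ND6 (log2 -1.25). Of 7 urothelial and epithelial genes 2 were at least 2-fold higher, KRT7 (log2 1.07) and KRT8 (log2 1.06), and 0 were when scaled to total counts. CDC20, an activator of mitotic exit, was also higher (log2 1.17), but 0 of the 30 mitosis genes were at least 2-fold higher with totals without the most abundant genes. The ratio of mutant to GST increased with transcript GC content, with a Spearman rho of 0.54 across genes. Genes with a UAUUUAU site lay below the others by -0.35 (-0.38 to -0.33), within the range of sets matched on 3' UTR length and composition (-0.38 to -0.32), and by -0.034 (-0.05 to -0.01) with the fit removed. The share of higher genes among those counted was 63.7% under TMM, 48.0% when scaled to total counts and 38.6% when scaled to totals without the most abundant genes, since these moved the median of all genes by -0.14 and -0.21.

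The direct comparison of wild-type and mutant ZFP36L1 asked what the alanine substitution altered in the recovered RNA. Of 23 cytokines and chemokines, 18 were higher with the wild-type protein and 2 lower. CXCL1 was 12.2-fold (log2 3.61, 3.57 to 3.65), CXCL2 10.2-fold (log2 3.35, 3.21 to 3.50) and TNF 7.28-fold higher (log2 2.86, 2.57 to 3.16). ZFP36L1 mRNA was 12.7-fold higher (log2 3.67, 3.61 to 3.73). Of the 33 known targets, a list that shares genes with the cytokines, 27 were higher and 1 lower, at 1.93 (1.31 to 2.22) above all genes. Of the hypoxia response genes 15 of 26 were higher and 5 lower. HIF1A was 2.17-fold higher (log2 1.12, 0.96 to 1.28) and E2F1 1.54-fold (log2 0.63, 0.56 to 0.69). HIF1A passed 2-fold here but not over GST, since it was lower with the mutant than with GST. CCND1 was at log2 -0.20 under TMM and at 0.12 when scaled to totals without the most abundant genes. Lower with the wild-type protein were 62 of 80 ribosomal protein genes, 28 of 40 respiratory chain genes and 20 of 30 proteasome genes, with GAPDH 25.1-fold lower (log2 -4.65, -4.69 to -4.61).

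In total, 4235 genes (30.1%) were higher and 5077 (36.1%) lower with wild-type than with mutant ZFP36L1. Scaling to total counts moved the median of all genes by 0.16, and totals without the most abundant genes moved it by 0.32. The balance turned with the latter, to 5187 higher and 4619 lower, and with TPM and a minimum mean TPM of 1 in place of the minimum count, to 4295 higher and 3879 lower. All 13 mitochondrially encoded mRNAs were measured, 8 of them were higher and none lower, with MT-ND3 at log2 3.07 and MT-ND2 at log2 2.45. Genes with a UAUUUAU site exceeded those without by 1.99 (1.90 to 2.08), against a median of 1.56 and a highest value of 1.65 in sets matched on 3' UTR length and composition. UAUUUAU ranked 24th of the 15460 heptamers as measured and 2nd with either fit removed. By number of sites, the median log2 ratio was -0.78 for 0 sites, 0.99 for 1, 1.43 for 2, 1.49 for 3 and 1.46 for 4 or more. With the fit on GC and length removed, the values were -0.30, 0.46, 0.40, 0.28 and 0.17, so that the median was highest at 1 site and did not increase with further sites. The ratio fell with transcript GC content (Spearman rho -0.67 across genes), from a median of 1.41 in the fifth of genes with the lowest GC content (median 38.0%) to -3.23 in the highest (60.9%).

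**Figure D3:**
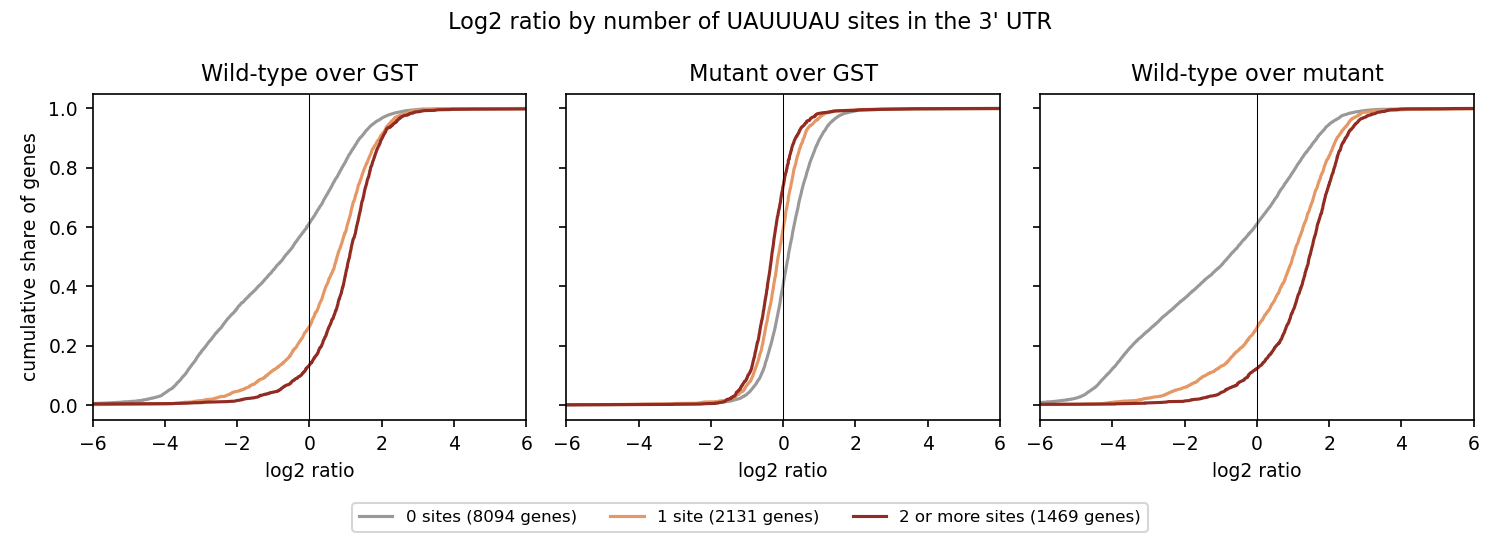
Cumulative share of genes (y axis) by log2 ratio (x axis) for genes with 0, 1, or 2 or more UAUUUAU sites in the 3' UTR, in each of the 3 comparisons. For wild-type over mutant the median was -0.78 for 8094 genes with 0 sites and 0.99 for 2131 genes with 1 site, and for mutant over GST the curves lay close together.

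**Figure D4:**
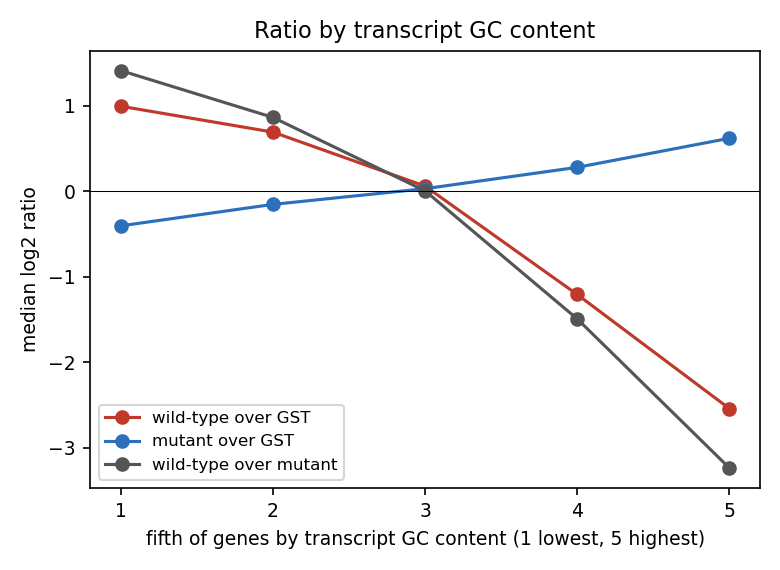
Median log2 ratio of genes in 5 groups of equal size by transcript GC content, from lowest to highest, for the 3 comparisons. Wild-type over GST went from 0.99 to -2.54, mutant over GST from -0.40 to 0.62, and wild-type over mutant from 1.41 to -3.23.

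Most genes higher with wild-type ZFP36L1 than with GST were also higher than with the mutant: 3106 genes, or 86.6%, were higher than in both, against 1079 if the lists were independent and 2.65 in simulated libraries without differences. These comparisons share the wild-type library, and GST and mutant lay close together (r 0.96), so a large overlap follows. Neither reference value allows for that. CXCL1, CSF2, TNF, NFKBIA and ZFP36L1 were among the 3106 genes. A further 4471 genes were lower with the wild-type protein than with both others, GAPDH, VIM and RPL27 among them. Relative to GST, 176 genes were higher with both proteins, where independent lists would give 323 and simulated libraries without differences gave 7.05. Another 769 were lower with wild-type and higher with mutant ZFP36L1, and 178 the other way round, numbers that rest on TMM scaling since the count of genes higher with the mutant was 1268 under TMM and 778 with totals without the most abundant genes. Across genes the ratio of wild-type to GST had a Pearson r of -0.16 (Spearman rho -0.32) with that of mutant to GST. Unchanged libraries that share the GST library gave 0.50 in simulation. Counting error was the only spread there, so 0.50 is not the r that sharing GST would give here. The covariance was -0.27, against 0.032 in that simulation. With the GST counts split at random between both ratios, r was -0.19. The sign of r depended on processing: it was 0.16 with the fit on GC and length removed, 0.17 without a minimum count and 0.23 for single transcripts.

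The genes with the most extreme ratios were mostly read in only part of the libraries. ADIPOR1, an adiponectin receptor, had 15235 estimated counts with wild-type ZFP36L1, 147 with GST and 0 with the mutant, so that it was 97.9-fold higher than GST and at least 4352-fold higher than the mutant (against a floor of 3 counts per library). LMNB2, a nuclear lamin, had 0 counts with wild-type ZFP36L1 and 127 with the mutant, and relative to GST it was at least 214-fold lower. CCDC61 had 432 with GST, 774 with the mutant and 0 with wild-type ZFP36L1, at least 152-fold lower than GST. MDH1, malate dehydrogenase, had 238, 5901 and 542 counts in the GST, wild-type and mutant libraries. PCDHGB6, a protocadherin, had 1, 2 and 657, giving a log2 ratio of mutant to GST of 8.92 (7.02 to 14.81). Of the 36 genes named for the highest and lowest ratios, 29 had under 3 counts in a library and 15 shared at least 20% of their 31-base sequences with other genes. Only 4 had neither feature, so these single-gene extremes are uncertain.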

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

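The tests of GC content and transcript length on the UAUUUAU genes and of construct RNA for ZFP36L1 were chosen only after the result was seen, as were the comparison of the site with other heptamers inside genes and the resampling of the heptamer rank.

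Groups of genes had medians on opposite sides with the wild-type and the mutant protein, each relative to GST. Cytosolic ribosomal proteins lay at -2.20 relative to all genes with wild-type ZFP36L1 and at 0.40 with the mutant, the respiratory chain at -2.21 and 0.42. Genes with a UAUUUAU site differed from those without by 1.63 with wild-type ZFP36L1 and by -0.35 with the mutant. The mutant value lay within the range of sets matched on 3' UTR length and composition (-0.38 to -0.32) and was -0.034 with the fit on GC and length removed, so it cannot be assigned to the site. With 1 library per protein, none of these 3 differences between the proteins was tested across replicates. Among the transcript identifiers that the annotation does not hold, 1813 had a mean of at least 10 counts, and 439 of them were at least 2-fold higher with wild-type ZFP36L1 than with GST, while 755 were lower.

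Genes with a UAUUUAU site in the 3' UTR were higher with wild-type than with mutant ZFP36L1 by 1.99. With a fit on transcript GC content and length removed the difference was 0.70 (0.63 to 0.75). This argues against those properties as the whole source only so far as the fit removed their trend. How well it did was not shown by the simulation, and the interval holds no error of the fit. Base composition of the 3' UTR alone is argued against by the rank of UAUUUAU, which was 1 of the 21 heptamers of 5 U and 2 A after the fit, at 0.70 against 0.55 for the next, and within the first 3 in 200 of 200 resamplings of genes. As measured, though, its rank was 8 of 21. Inside 795 genes, transcripts with the site exceeded transcripts of the same gene without it by a median of 1.34 (1.08 to 1.55), as recognition of the site by the wild-type protein would predict, but the other 20 heptamers gave a median of 1.09 and UAUUUAU came 2nd of the 21, so this test may reflect A- and U-rich sequence in general.

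In the 3796 genes without AUUUA in the 3' UTR the ratio of wild-type to mutant ZFP36L1 also fell with GC content (Spearman rho -0.67). A GC bias in library preparation could act along the whole transcript, and the partial rank correlation with GC content upstream of the 3' UTR, at fixed 3' UTR GC, was -0.26 (-0.29 to -0.23). With 3' UTR GC content at fixed upstream GC it was -0.38 (-0.41 to -0.35), farther from 0, so the test pointed neither way. For mutant over GST the upstream value was 0.24 (0.21 to 0.27) and the 3' UTR value 0.25 (0.22 to 0.28). A bias of the wild-type library and a preference of the protein for A- and U-rich RNA cannot be told apart here, since 1 library stands for each protein. No biological explanation of this gradient was tested.

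ZFP36L1 mRNA was 11.2-fold higher with wild-type ZFP36L1 than with GST. RNA left from the expression construct should appear with the mutant fusion too, which shares the coding sequence, but the mutant stood at 0.879-fold of GST (0.832 to 0.927), which argues against this source provided both fusions were prepared alike. Reads shared with other annotated genes are argued against by the share of its 31-mers found in their transcripts, 0%. Transcript identifiers that the annotation does not hold were not searched, so sharing with those stays open. Also open are binding of the endogenous mRNA, which has 3 sites in its 3' UTR, as a hypothesis, and carry-over specific to the wild-type preparation.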

How the results depend on the processing

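The removal of the GC and length fit and of genes under 3 counts in a library were chosen only after the data had been seen. Of 175 alternative values over 14 results and 16 settings, 21 could not move, since rescaling a library leaves medians relative to all genes and the correlation as they are. Of the other 154, 107 stayed within the limits set, with the same sign where a value has one, 44 moved and 3 reversed. Numbers of higher or lower genes have no sign and could not reverse. Each was judged alone, so a balance could turn among values that stayed. For mutant over GST, 1268 were higher and 722 lower under TMM, but 939 and 1016 when scaled to total counts. The 107 include the UAUUUAU differences for protein-coding genes only. These could not move either, since only protein-coding transcripts had entered that comparison. The median of the known targets relative to all genes kept its direction in each setting that could move it, from 1.70 to 2.34 for wild-type over GST, from 1.77 to 2.49 for wild-type over mutant and from -0.23 to -0.10 for mutant over GST. The cause was not tested unless stated. No paired analysis was possible because the labels give 1 library per group, and for the same reason no library could be left out. Depth set the width of the intervals: for mutant over GST it was -0.52 to 0.24 for TNF, with 131 and 108 counts in GST and mutant, and -0.46 to -0.36 for CXCL1, with 7660 and 5231.

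Scaled to totals without the most abundant genes, 778 genes were higher and 1237 lower for mutant over GST. From TPM, where a minimum mean TPM of 1 also replaced the minimum count, 548 were higher for mutant over GST, the UAUUUAU differences were 1.51, -0.27 and 1.81 for wild-type over GST, mutant over GST and wild-type over mutant, and the correlation of the GST ratios was -0.21. Without a minimum count 1167 genes were lower for mutant over GST, the UAUUUAU differences were 1.47 for wild-type over GST and 1.78 for wild-type over mutant, and the correlation was 0.17, reversed. With a minimum of 100 counts fewer genes entered, and 581 were higher and 362 lower for mutant over GST, the UAUUUAU difference for wild-type over GST was 1.73 and the correlation -0.38. For protein-coding genes the correlation was -0.25.

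For single transcripts, of which more entered than of genes, 7259 were higher and 11281 lower for wild-type over GST, 4911 and 4000 for mutant over GST, and 8297 and 11913 for wild-type over mutant, with 6041 higher than in both. The known targets then stood at 2.24 for wild-type over GST and 2.49 for wild-type over mutant, the UAUUUAU differences were 2.11, -0.42 and 2.75, and the correlation was 0.23, reversed. By construction, stricter limits gave fewer genes: with the interval bound at 2-fold, 543 higher and 228 lower for mutant over GST, and at 4-fold 746 higher for wild-type over GST, 175 higher and 141 lower for mutant over GST, 1325 higher for wild-type over mutant and 519 higher than in both. With UUAUUUAUU as the motif the differences were 1.09, -0.24 and 1.3. With the GC and length fit removed, 575 genes were higher for mutant over GST, the known targets stood at 2.34 and 2.48 for wild-type over GST and over mutant, the UAUUUAU differences were 0.65, -0.034 and 0.70, and the correlation was 0.16, reversed. Without genes under 3 counts in a library the correlation was -0.29.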

Other observations

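The comparison of sequence sharing between genes was the test in this part chosen only after the pattern had been seen, though before its own result was known.

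Several groups not described so far held genes on both sides when wild-type ZFP36L1 was compared with GST. Of 16 interferon response genes 8 were lower and 1 higher, at -0.80 relative to all genes (14.3rd percentile of matched lists), with the membrane protein IFITM3 at log2 -3.80 and the ubiquitin-like ISG15 at log2 -3.36. Of 13 histone genes 5 were lower and 2 higher (list at -0.30), with HIST1H1C at log2 -4.20 and HIST2H2BE at log2 1.59. Of 11 mesenchymal markers 5 were lower and 1 higher (-0.36), with the intermediate filament VIM at log2 -4.09 and fibronectin FN1 at log2 1.21. Of 7 urothelial and epithelial markers 3 were lower, such as the keratin KRT18 (log2 -4.06), and 3 higher, such as the nuclear receptor PPARG (log2 2.53), with the list at -0.11. Of 20 housekeeping genes 7 were lower and 5 higher (-0.30), and ACTB stood at log2 -0.10 under TMM and 0.01 when scaled to totals without the most abundant genes.

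Mitochondrially encoded mRNAs were higher in 3 of 13 cases and lower in none with wild-type ZFP36L1 than with GST (0.55 relative to all genes), with MT-ND3 at log2 2.36. Of 9 abundant non-coding RNAs 1 was higher, the snoRNA host SNHG8 (log2 2.96), and none lower (0.30). Among 18 markers of leukocytes, erythroid cells and hepatocytes only LYZ was measured, with 13, 7 and 13 counts in the GST, wild-type and mutant libraries. The remaining list positions for wild-type over GST were 0.84 for p53 targets, 0.53 for the NF-kB pathway, 0.36 for proteins that bind AU-rich elements, 0.32 for mitosis, 0.30 for G1/S and -0.18 for decay machinery, each relative to all genes.

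There were 59 protein-coding genes with under 3 counts in 1 library and at least 100 in another, and the lowest library was wild-type ZFP36L1 for 47, GST for 8 and the mutant for 4. Their median share of 31-mers found in other genes was 12.9%, against 3.47% in 500 genes of like expression. Of the 59 genes 24 shared at least 20%, against 69 of the 500 (13.8%), and 22 shared under 5%. Sharing was thus more frequent than in genes of like expression. The median lay between the limits of 5% and 20%, so the test pointed neither way for the group as a whole. AC012254.2, with 1076 counts in the wild-type library and 0 in both others, shared 95.4%, and CCDC61 shared 0%. Sharing with transcript identifiers that the annotation does not hold was not searched.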
